A study of Mus musculus with 6 samples.

How the data were processed

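The samples were 6 RNA preparations from Lineage- c-Kit+ Sca1+ (LSK) bone marrow cells of mice, a flow-sorted fraction that holds the blood stem cells and the earliest multipotent progenitors. Of these, 3 came from mice in which miR-21 had been deleted in blood cells (floxed miR-21 with the Mx1-Cre transgene) and 3 from littermates with the same floxed alleles and no Cre. Per the labels' protocols, both groups received 250 µg of pIpC per injection, 7 injections in all, starting at an age of 4 to 6 weeks, and cells were taken 4 weeks later. The double-stranded RNA analogue pIpC raises interferon, which switches on the Mx1 promoter and so the Cre recombinase. Labelled cDNA was prepared from 250 ng of total RNA and hybridised to Affymetrix arrays. Groups and replicate numbers were taken from the sample titles, which call the samples biological replicates. Whether a replicate was a single mouse or several is not given in the sources used here, so the p-values measure only the spread between these arrays.

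The authors deposited 1 table of log2 values, 1 column per array, and RMA is the tool named in the submitters' processing notes. RMA as a method corrects background, forces the same intensity distribution on all arrays and summarises probes into probe sets, so that a change shared by most transcripts would be removed before deposit. The log base is not given in the sources used here. It was read as 2 from the range of the values, which ran up to 11.5. The software version and genome build are also not given in the sources used here. Medians per array lay between 1.89 and 1.95, so no array stood apart in overall level. For arrays there is no count behind a value, and their number, 3 per group, limits the precision.

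Genes were named through the platform annotation of GEO, with symbols updated by Entrez ID through a RefSeq gene table of assembly GRCm38.p6. Of 65956 probe sets, 31080 had 1 gene, 1670 had several and 33206 were not listed. Symbols changed for 841 probe sets, and 23430 of the probe sets with 1 gene had their Entrez ID in the RefSeq table. No gene was named from a probe set with several genes, except to report the probe set that covers the deleted locus. Where 1 of the 30627 symbols had more than 1 probe set (357 symbols), the brightest over all 6 arrays was used. Genes with a mean over the 6 arrays under the median of all probe sets, 1.92 on the log2 scale, were left out as dim, which removed 11617 genes and kept 19010.

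Knockout and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. Every change is the mean log2 value of the knockout arrays minus that of the control arrays. A change given with ± has the standard error from limma after it, and a group mean given with ± has the SD. A second count used a fold of at least 1.5 with an unadjusted p under 0.05. Predefined gene lists with at least 5 tested members were compared with all other genes by camera at its preset inter-gene correlation of 0.01, adjusted over the 33 lists tested, and again with an estimated correlation. Fry was a further alternative, which asks only whether the genes of a list move on balance in 1 direction. Members that pass are counted over all genes and adjusted over the list alone. For the probe set of the deleted locus an exact two-sided permutation test was used as well.

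The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named the miR-21 locus, the 10 highest and 10 lowest changes among passing genes without provisional symbols, non-coding small RNA genes, olfactory and vomeronasal receptors and antigen receptor segments, up to 4 members of each list by p with its largest and smallest change, and a set always reported, of which 1 item is not reported here: Pdcd4, Spry1, Spry2, Btg2, Tgfbr2, Rela, Nfkb1, Nfkbia, Tnfaip3, Cdkn1a, Cdkn1c, Mki67, Kit, Ly6a, Procr, Mpo, Flt3 and Mx1. Of these, Nfkb1 and Ly6a (the Sca-1 gene) had no probe set of their own in the annotation and Mx1 was dim. Other genes named in the text are members of the lists, chosen as examples after their values were seen.

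The gene lists were miR-21 targets, NF-kB target genes, NF-kB pathway components, stem cell enriched genes, lymphoid-primed, myeloid and megakaryocyte-erythroid progenitor genes, G1/S replication, G2/M mitosis, quiescence and CDK inhibitor genes, p53 response, apoptosis, interferon response, immediate early and stress genes, oxidative phosphorylation, glycolysis and hypoxia, antioxidant genes, ribosome biogenesis and Myc targets, TGF-beta and BMP pathway, PI3K-AKT-mTOR pathway, DNA damage repair, ER stress, genes neighbouring the miR-21 gene, and replication-dependent histones. Marker lists covered B, plasma, T and NK cells, neutrophils, monocytes and macrophages, dendritic cells, mast cells and basophils, eosinophils, erythroblasts, megakaryocytes and platelets, endothelial and stromal cells, sex-linked genes and mitochondrially encoded RNA.

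Alternatives were no filter and a filter at the 70th percentile, a second quantile normalization, centring each array on its median, the mean of a gene's probe sets, an intensity trend with robust variance, array weights, the replicate number as a block, leaving out each array in turn, other fold and p thresholds, and the other set tests. The scripts were tested on simulated data made from the means and variances of the 19010 genes, with 200 genes changed in each of 20 runs. Genes changed by 0.5 on the log2 scale were recovered in 96.4% of cases and those changed by 1 in 100%, and 5.98% of the calls were false. A list of 40 genes lowered by 0.3 was found in 20 of the 20 runs, and on average 0.1 lists passed without any change. These simulations drew genes independently, so they do not test the assumption of a preset correlation. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. A planned test of genes with miR-21 seed sites in their 3' UTRs was not run, since no genome sequence was used here.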

Results

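Expression of 19010 genes was compared between LSK cells of 3 miR-21 knockout and 3 control samples, each on 1 array. The LSK fraction of bone marrow is enriched for blood stem cells. The comparison addresses which transcripts differ between these cells from knockout and control mice. The knockout was made to lack miR-21, a microRNA known to repress targets such as Pdcd4. Only knockout mice carried the Cre transgene, so effects of Cre cannot be told apart from those of miR-21 loss. Arrays of the same group had correlations across all probe sets of 0.995 to 0.997, and arrays of different groups 0.987 to 0.991. The first principal component held 73.8% of the variance and separated the groups, and the second held 10.9%.

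The deleted locus was looked at first. The miR-21 gene (Mir21a) lies at the end of its host gene Vmp1, and 1 probe set was annotated to both. It had a log2 value of 5.68 ± 0.07 (SD, n = 3) in the knockout and 5.63 ± 0.02 (SD, n = 3) in control, a difference of 0.05 with an exact two-sided permutation p of 0.4, where 3 arrays against 3 cannot go below 0.1. Since this probe set spans the host gene, it does not check the deletion.

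Myeloid progenitor genes rose in the knockout LSK cells (18 of 23, camera adjusted p = 4.28e-09, adjusted p = 0.130 with an estimated correlation). Targets of NF-kB fell (26 of 44, camera adjusted p = 1.46e-12, adjusted p = 0.114 with an estimated correlation). Among single genes, with provisional symbols, small RNA genes, olfactory and vomeronasal receptors and antigen receptor segments left out of the ranking, the highest change was that of Ms4a3, a marker of granulocyte-monocyte progenitors, at 3.20 ± 0.10 (SE, 9.16-fold, adjusted p = 5.28e-07). It was followed by the protease inhibitor Stfa1 at 3.09, Igsf6 at 2.55, the calcium-binding S100a8 at 2.38, Trem3 at 2.27, haptoglobin (Hp) at 2.22, the basophil protease Mcpt8 at 2.06 and neutrophil elastase (Elane) at 2.06. The other genes among the 10 highest were Wfdc21 at 1.97 and Cstdc6 at 1.95. The control means of Stfa1 (1.14) and Cstdc6 (1.67) lay under the dim level of 1.92, so the sizes of these changes, and their ranks, are uncertain. In the same ranking, the lowest was Il1r2, the decoy receptor for interleukin-1, at -3.28 ± 0.07 (SE, 9.71-fold lower, adjusted p = 5.11e-08). Next came the Notch effector Hey1 at -2.39, thrombospondin 1 (Thbs1) at -2.27, the costimulatory molecule Cd86 at -2.18, Plk2 at -2.16, the chemokine Cxcl2 at -2.09, the inflammasome gene Nlrp3 at -2.02, Rora at -2.01 (-0.92 as the mean of its probe sets), Vegfa at -1.89 and Zbtb10 at -1.83.

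**Figure D1:**
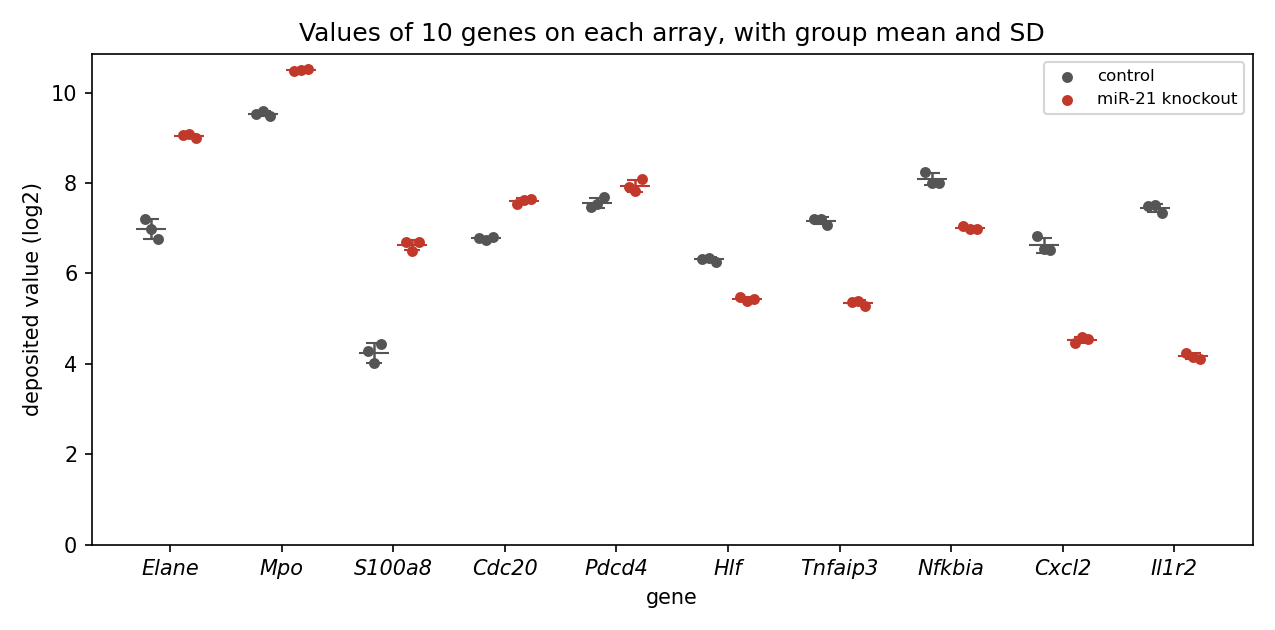
Deposited log2 values (vertical axis) of 10 genes (horizontal axis) on each of the 6 arrays, with the mean and SD of the 3 control arrays (grey) and the 3 knockout arrays (red). The arrays of both groups do not overlap for any of these genes, and the mean of Elane was 9.05 in the knockout and 6.99 in control, that of Il1r2 4.17 and 7.45.

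In all, 5907 genes (31.1%) passed the adjusted threshold in limma, 3630 of them higher and 2277 lower in the knockout. Most changes were small, with a median size of 0.34 among the genes that passed. With a fold of at least 1.5 there were 334 higher and 445 lower, and with a fold of at least 2 there were 85 and 131. At an unadjusted p and a fold of at least 1.5, 783 genes passed (338 higher, 445 lower). The values of the groups did not overlap for 47.9% of the genes, against 10% by chance. The split by direction depended on scaling, since 2750 genes were higher and 2719 lower when each array was centred on its median, and without knockout replicate 3 the number of higher genes was 2322.

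Targets of NF-kB, the transcription factor of inflammatory signalling, fell in the knockout. Of 44 tested, 26 fell, 3 rose and 15 did not pass, with a median change of -0.32 (camera adjusted p = 1.46e-12, adjusted p = 0.114 with an estimated correlation). The median was -0.51 with the stricter filter on dim genes. Adjusted over the list alone, 29 fell and 4 rose. Beside Cxcl2, large falls were seen for the inhibitor of the pathway Tnfaip3 (-1.81 ± 0.06, adjusted p = 8.79e-07), prostaglandin synthase Ptgs2 (-1.75) and the urokinase receptor Plaur (-1.64), and Nfkbia, which encodes the inhibitor IkB-alpha, fell by 1.07. The proteins of Nfkbia and Tnfaip3 restrain the pathway themselves. Myc, also a target, rose by 0.81.

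Components of the NF-kB pathway moved both ways. Of 27, 12 fell, 5 rose and 10 did not pass (median -0.15, camera adjusted p = 0.00347, adjusted p = 0.233 with an estimated correlation), and adjusted over the list alone 13 fell and 7 rose. A version without members of the NF-kB target list was chosen after the data had been seen. In it, 9 of 23 fell, 5 rose and the median was -0.04. Malt1 at -1.81, Rel at -1.23, Nfkb2 at -1.10 and Rela, the p65 subunit, at -0.56 ± 0.06 (adjusted p = 2.33e-04) fell, while the adaptor Myd88 rose by 0.52.

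Predefined miR-21 targets did not rise as a group. Among 44 tested, 4 rose, 17 fell and 23 did not pass, with a median of -0.14 (camera adjusted p = 1.28e-05, adjusted p = 0.130 with an estimated correlation). Adjusted over the list alone, 8 rose and 20 fell. The genes that rose were Pdcd4, a translation inhibitor, from 7.56 ± 0.11 to 7.94 ± 0.13 (SD, n = 3 each, change 0.38, limma adjusted p = 0.00931), Il12a (0.46), Klhl42 (0.35) and Cdc25a (0.24). The call on Cdc25a was lost without knockout replicate 1 or 3 or control replicate 2 or 3 (change 0.18 to 0.25). Falls were seen for Map2k3 (-1.04), Fbxo11 (-0.94), the receptor tyrosine kinase antagonists Spry2 (-0.89) and Spry1 (-0.29), the TGF-beta receptor Tgfbr2 (-0.82) and Smad7 (-0.76). That of Spry1 was lost without knockout replicate 1 or 3 or control replicate 2 (-0.26 to -0.23). Btg2 was at -0.16 with an adjusted p of 0.0735, and at -0.20 with an adjusted p of 0.0411 when each array was centred on its median. After the data had been seen, members shared with some other lists were left out. Those lists were the NF-kB target, TGF-beta and BMP, lymphoid-primed, quiescence, immediate early and p53 lists. Then 4 of 36 rose and 11 fell, and the median was -0.06.

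TGF-beta and BMP pathway genes fell, with 12 of 26 lower, 2 higher and 12 not passing (median -0.18, camera adjusted p = 7.94e-07, adjusted p = 0.140 with an estimated correlation). Adjusted over the list alone, 14 fell and 2 rose. The repressors Skil (-1.45) and Tgif1 (-0.81) fell along with Tgfbr2, Smad7 and the receptor Bmpr2 (-0.67).

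Genes enriched in stem cells fell. Of 40 tested, 21 fell, 5 rose and 14 did not pass (median -0.26, camera adjusted p = 3.17e-06, adjusted p = 0.114 with an estimated correlation), and over the list alone 22 fell and 7 rose. Angpt1 (-0.93), the transcription factor Hlf (-0.88 ± 0.06, adjusted p = 1.35e-05), Mmrn1 (-0.82), Fgd5 (-0.60), Mecom (-0.48), Meis1 (-0.48), the stem cell factor receptor Kit (-0.46) and Procr (-0.46) fell. Slamf1, which encodes the stem cell surface marker CD150, rose by 0.54 and Gfi1 rose by 0.38, while Cdkn1c, a cell cycle inhibitor, was at 0.14 with an adjusted p of 0.179. Genes of lymphoid-primed progenitors fell likewise, 10 of 19 lower, 1 higher and 8 not passing (median -0.27, camera adjusted p = 3.17e-06, adjusted p = 0.114 with an estimated correlation). Adjusted over the list alone, 12 fell and 2 rose. Lax1 (-1.01), Mef2c (-0.74), Satb1 (-0.57) and the cytokine receptor Flt3 (-0.47) fell and Cd48 rose by 0.42 (0.34 and no longer passing without knockout replicate 3).

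Myeloid progenitor genes rose. Of 23, 18 rose, 2 fell and 3 did not pass (median 0.85, camera adjusted p = 4.28e-09, adjusted p = 0.130 with an estimated correlation), and adjusted over the list alone 19 rose and 2 fell. Beside Ms4a3 and Elane, the granule proteases Ctsg (1.71) and Prtn3 (1.53), the Fc receptor Fcgr3 (1.29) and myeloperoxidase (Mpo, 0.97 ± 0.06, adjusted p = 7.75e-06) rose, while Cd33 (-0.85) and the G-CSF receptor Csf3r (-0.34) fell. Neutrophil markers, which late precursors of neutrophils hold as well, moved with them, although a lineage-negative sort would remove mature neutrophils. All 12 that were tested rose (median 1.03, camera adjusted p = 7.38e-11, adjusted p = 0.130 with an estimated correlation), and over the list alone 12 rose. S100a9 rose by 1.57, Ngp by 1.27, Ltf by 1.02 and Camp by 0.99.

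Megakaryocyte-erythroid progenitor genes rose, with 13 of 23 higher, 3 lower and 7 not passing (median 0.30, camera adjusted p = 0.0132, adjusted p = 0.233 with an estimated correlation). Adjusted over the list alone, 15 rose and 3 fell. Carbonic anhydrase 1 (Car1) rose by 0.99, Mfsd2b by 0.85 and the integrin Itga2b by 0.56, and Cnrip1 fell by 0.60. Of 7 mast cell and basophil markers, 5 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone (median 0.79, camera adjusted p = 0.0118, adjusted p = 0.233 with an estimated correlation). Fcer1a rose by 1.37, from a control mean of 1.70 that lay under the dim level, and Cpa3 by 0.79, and Gzmb fell by 0.50. With no filter on dim genes, which adds further members of this list, its median was 0.13 (camera adjusted p = 0.00916).

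Genes of both cell cycle lists rose. Of 36 G2/M genes, 29 rose, 0 fell and 7 did not pass (median 0.47, camera adjusted p = 7.38e-11, adjusted p = 0.233 with an estimated correlation), and adjusted over the list alone 31 rose. The mitotic kinases Aurka (0.88 ± 0.08, adjusted p = 6.58e-05) and Plk1 (0.81), Kif22 (0.88) and Cdc20 (0.83) rose. The proliferation marker Mki67 rose by 0.24, and was at 0.14 with an adjusted p of 0.144 after a second quantile normalization and lost its call without knockout replicate 1 or 3 or control replicate 1 or 2 (0.20 to 0.23). Among 37 G1/S genes, 20 rose, 2 fell and 15 did not pass (median 0.22, camera adjusted p = 0.00153, adjusted p = 0.506 with an estimated correlation), with 22 and 2 adjusted over the list alone. Gins3 (0.67), E2f2 (0.47), Rrm2 (0.41) and Ccne1 (0.39) rose, and Orc1 fell by 0.47. Quiescence and CDK inhibitor genes fell, 10 of 25 lower, 1 higher and 14 not passing (median -0.16, camera adjusted p = 3.10e-05, adjusted p = 0.181 with an estimated correlation), and 12 fell and 3 rose adjusted over the list alone. The median was -0.10 with the mean of all probe sets of a gene and -0.09 without knockout replicate 2. Falls were seen for the nuclear receptors Nr4a2 (-1.49) and Nr4a1 (-1.10), the antiproliferative Btg1 (-1.24), the p21 gene Cdkn1a (-1.08 ± 0.06, adjusted p = 4.76e-06) and Foxo1 (-1.04).

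**Figure D2:**
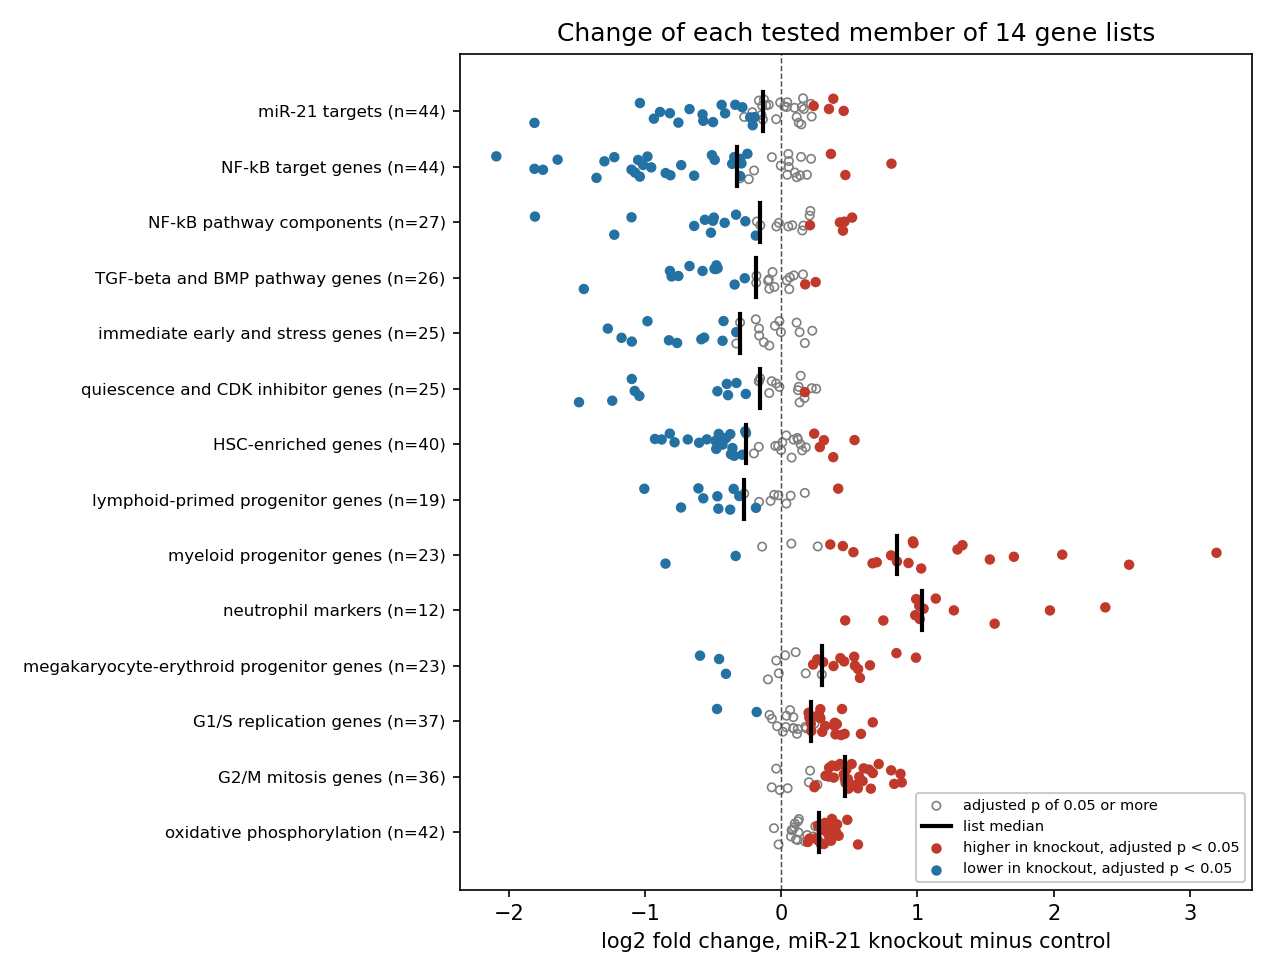
Change of each tested member (points) of 14 lists (rows), as the log2 value of knockout minus control, with the list median as a black bar. Red and blue points passed an adjusted p of 0.05, open points did not. The medians ran from -0.32 for NF-kB targets to 1.03 for neutrophil markers.

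Immediate early and stress genes fell, 11 of 25 lower, 0 higher and 14 not passing (median -0.30, camera adjusted p = 1.18e-08, adjusted p = 0.181 with an estimated correlation), and 14 fell adjusted over the list alone. The median was -0.19 with array weights, without knockout replicate 2 and without control replicate 1. Atf3 (-1.27) and the phosphatase Dusp5 (-1.17) fell along with Nr4a1, whereas Fos was at -0.09 (adjusted p = 0.241, or -0.19 and 0.0237 after a second quantile normalization), Jun at -0.05 (adjusted p = 0.569) and Dusp1 at 0.23 (adjusted p = 0.261). Oxidative phosphorylation genes rose, 26 of 42 higher, 0 lower and 16 not passing (median 0.28, camera adjusted p = 3.17e-06, adjusted p = 0.540 with an estimated correlation), and 27 rose adjusted over the list alone. Examples were Ndufs8 (0.56), Cox5a (0.48) and Uqcrc1 (0.41). Interferon response genes went both ways, with 11 of 38 lower, 6 higher and 21 not passing, and the same counts of 11 and 6 adjusted over the list alone (median -0.08, camera adjusted p = 0.0221, adjusted p = 0.506 with an estimated correlation). The RNA sensor gene Ddx58 (-0.49), Usp18 (-0.41) and Oas2 (-0.38) fell, and Igtp (0.41) and Stat2 (0.33) rose. The call on this list was also lost with the stricter filter on dim genes (camera adjusted p = 0.0918), after a second quantile normalization (0.0510), with fry in place of camera (adjusted p = 0.193), without knockout replicate 2 (0.0583) and without control replicate 1 (0.0895).

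Markers of other cell types did not pass camera as lists. The counts were 2 higher and 0 lower of 9 monocyte and macrophage markers (median 0.11, adjusted p = 0.199), 2 and 1 of 6 plasma cell markers (median 0.13, adjusted p = 0.517), 1 and 1 of 7 T cell markers (median 0.06, adjusted p = 0.769) and 1 and 1 of 6 dendritic cell markers (median 0.10, adjusted p = 0.963). Of 8 megakaryocyte and platelet markers, 3 rose and 2 fell (median 0.13, mean -0.19, adjusted p = 0.963). Of 8 endothelial markers, 0 rose and 2 fell (median 0.01, mean -0.12, adjusted p = 0.361), and of 7 stromal markers 2 rose and 0 fell (median 0.12, adjusted p = 0.239). For T cell markers the camera direction was down although median and mean were above 0. Adjusted over the list alone, these 7 counts were the same. Lists with under 5 tested members had no set test. They were B cell markers (1 of 4 rose), NK cell markers (2 of 3 rose, 1 fell), eosinophil markers (3 of 4 rose) and erythroblast markers (0 of 4 passed).

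All 18 lists that passed camera at its preset correlation, 8 of them higher and 10 lower, lost the call with an estimated correlation, and 22 of the 33 lists passed fry. With 3 arrays per group the estimate of a correlation is itself imprecise. The estimate was under the preset 0.01 for the stem cell (0.0092), lymphoid-primed (-0.005) and histone (-0.0625) lists. It was above 0.01 for the other lists that passed. A higher correlation therefore does not account for the calls lost by the stem cell, lymphoid-primed and histone lists. For the stem cell list the unadjusted camera p went from 7.04e-07 to 0.0074 with an estimate under the preset. The calls lost by the other lists can therefore not be put down to correlation alone.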

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

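Beyond the genes compared above, 2 kinds of probe set on the same arrays carried differences between the groups, and both stand here because they lie outside the comparisons reported. Among 12759 probe sets above the dim level with no gene in the annotation, 770 were higher in the knockout and 2404 lower in a limma fit of all probe sets above the dim level, adjusted over those probe sets and not over the genes compared above. Among 966 probe sets annotated to several genes, 163 were higher and 92 lower in that fit. No explanation was tested for either count.

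The 6 arrays can be divided into 3 and 3 in only 10 ways, so that the share of splits with a result as large cannot go under 0.1. The real split gave 5907 genes at the adjusted threshold and the highest of the others 0, with 1 of 10 splits as large. For genes with a fold of at least 1.5 at an unadjusted p the values were 783 and 5, again 1 of 10. For lists passing camera they were 18 and 13, also 1 of 10. Each of the other splits puts 2 arrays of a genotype and 1 of the other on each side, so part of the genotype difference stays in it, and the 13 lists are not a value without any effect. With this same mix the other splits passed 0 to 13 lists, and 0 genes in each. Spread between arrays therefore also adds to the number of lists that pass camera. The outcome of these splits had not been seen when the test was chosen.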

How the results depend on the processing

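Of the alternatives, 1 was chosen after the data had been seen, the miR-21 and NF-kB lists without members shared with some other lists. No gene called in the main comparison reversed in any of the 14 alternative fits, and calls ranged from 4138 to 7167, against 5907. Without filter there were 5450, at the 70th percentile 5393, after quantile normalization 6332, after centring 5469, and 5908 with the mean of all probe sets of a gene, where 17 calls were lost. An adjusted threshold of 0.1 gave 7703. Leaving out 1 array gave 4138 to 5115 calls, with 2322 to 3093 higher genes. The lowest of these came without knockout replicate 3, and the cause was not tested.

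With a fold of at least 2 or 1.2 in place of 1.5, 216 or 4725 genes passed with an unadjusted p, by construction. The number of lists passing was 16 to 19 across the fits and 0 with an estimated correlation. A higher correlation does not account for this in the stem cell and lymphoid-primed lists, whose estimates (0.0092 and -0.005) lay under the preset 0.01. In the other lists a higher correlation cannot be taken as the only cause, since p also rose where the estimate was lower. The cause was not tested further. With an estimated correlation the medians of the main lists, -0.14 for miR-21 targets, -0.32 for NF-kB targets, -0.15 for NF-kB components, -0.26 for stem cell genes, 0.22 for G1/S and 0.47 for G2/M, stay as they are and their calls are lost. Without members of the immediate early and p53 lists, NF-kB targets had a median of -0.30. Members of the miR-21 target and NF-kB component lists, such as Tnfaip3 and Rel, stayed in. Without members of the NF-kB target list, NF-kB components had a median of -0.04. The shift of p53 response genes, a median of -0.02, was -0.0623 to 0.029 with 1 array left out, above 0 without knockout replicate 3 (0.029) and without control replicate 1 (0.0029), and the cause was not tested. Among values of named genes under the alternatives, 1717 kept call and direction, 13 lost the call (Mki67, Cdc25a, Spry1 and Cd48) and 2 gained it (Btg2 and Fos).

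Replicate numbers are shared by the groups. Deviations from the group means correlated over genes at 0.219, 0.333 and 0.09999 for the pairs of equal number, and at -0.277 to 0.129 for the others. Knockout replicate 3 correlated best with control replicate 1 (0.129). The labels do not say that equal numbers share a litter, day or animal, so the main fit did not take them as pairs. An effect shared by equal numbers stays open. With a replicate block, 7167 genes passed (4549 higher, 2618 lower) and 18 lists. The seed site test and its alternatives were not run. Signal near background limits the dim genes, of which 11617 were left out.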

Other observations

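The tests of explanations in this part were chosen after the results had been seen. Further lists held genes that changed in both directions. In the p53 list, 6 of 27 fell and 3 rose, with the same counts adjusted over the list alone (median -0.02, mean -0.23, camera adjusted p = 0.0183, adjusted p = 0.330 with an estimated correlation). Plk2 (-2.16), Tnfrsf10b (-1.55), Plk3 (-1.44), Cdkn1a (-1.08) and Fas (-1.01, or -0.42 as the mean of its probe sets) fell and Gadd45a rose by 0.35. The list median was above 0 without knockout replicate 3 (0.029) and without control replicate 1 (0.0029). Of 26 apoptosis regulators, 5 rose and 5 fell, also over the list alone (median 0.12, mean -0.03, camera direction down, adjusted p = 0.830). Bcl2l11, which encodes the death-promoting protein Bim, fell by 1.13 and Birc3, a survival gene, by 0.96, while cytochrome c (Cycs) rose by 0.50. Of 26 glycolysis and hypoxia genes, 7 rose and 7 fell, and 8 and 8 over the list alone (median 0.09, mean -0.08, camera direction down, adjusted p = 0.336). Vegfa, the glucose transporter Slc2a3 (-0.76) and Hif1a (-0.57) fell, while the enzymes Pgam1 (0.45) and Ldha (0.36) rose. Of 5 replication-dependent histone genes, 4 rose and 1 fell, also over the list alone (median 0.72, camera adjusted p = 0.0175, adjusted p = 0.181 with an estimated correlation). H1f1 rose by 0.89 and H1f2 fell by 0.72.

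The remaining lists did not pass camera. Antioxidant genes had 10 of 23 higher and 2 lower, 12 and 4 adjusted over the list alone (median 0.17, adjusted p = 0.160). Ribosome biogenesis and Myc targets had 8 of 30 higher and 5 lower, 8 and 6 over the list alone (median 0.08, camera direction down, adjusted p = 0.963). PI3K-AKT-mTOR genes had 4 of 23 higher and 7 lower, 5 and 7 over the list alone (median -0.04, adjusted p = 0.0616, and adjusted p = 0.0268 without control replicate 3). DNA damage repair genes had 5 of 24 higher and 3 lower, 6 and 3 over the list alone (median 0.07, adjusted p = 0.963). ER stress genes had 4 of 22 higher and 4 lower, 6 and 4 over the list alone (median 0.10, adjusted p = 0.846). Of 12 genes neighbouring the miR-21 gene, 3 rose and 4 fell, also over the list alone (median 0.04, mean -0.02, camera direction down, adjusted p = 0.428). Of 3 sex-linked genes tested, all Y-linked, 2 fell. On the 6 arrays these lay between 3.55 and 4.44, and Xist was under the dim level (0.94 to 1.10), so no array showed a female pattern. In the list of mitochondrially encoded RNA 2 members were tested, mt-Rnr1 and Gm10925, which came in through a synonym, and 0 passed. In a limma fit of all probe sets above the dim level, adjusted over those probe sets and grouped by class in the RefSeq table, 190 of 394 small nuclear RNA probe sets fell and 11 rose (median -0.27), while 795 of 2557 pseudogene probe sets rose and 75 fell (median 0.19).

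The fall of NF-kB target genes was set against technical explanations. Fewer mature granulocytes in the knockout sort would lower neutrophil markers, and the median of these was 1.03 (95% bootstrap interval 0.99 to 1.42). That argues against fewer cells with these transcripts. Late precursors hold the same transcripts, so a loss of mature cells alone stays open. A stronger handling response in the control cells may remain, since immediate early genes outside the NF-kB list fell as well, with a mean of -0.35 against -0.50 for NF-kB targets, a difference of 0.16 (permutation p = 0.324). A general loss of short-lived or unprocessed RNA would lower probe sets without a listed gene about as much as NF-kB targets (median -0.32). Their median was -0.0073 (95% bootstrap interval -0.0121 to -0.0028), much nearer to 0 than that of NF-kB targets. The bound set against this explanation was a median of 0 or above, which was not met. RMA would also remove a loss shared by most transcripts, so this median cannot decide on a general loss. A loss in part of these probe sets stays open as well, as 2404 were lower and 770 higher. By class, medians were -0.27 for small nuclear RNA (190 of 394 lower, 11 higher), 0.05 for microRNA, 0.03 for small nucleolar RNA and 0.06 for long non-coding RNA. An effect of the genotype (miR-21 loss or Cre) on the pathway remains a hypothesis beside these.

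The rise of myeloid genes was treated in the same way. Carry-over of mature neutrophils is argued against for the azurophil granule genes Mpo, Elane, Prtn3 and Ctsg, which mature neutrophils no longer transcribe and whose lowest change was 0.97 (highest adjusted p = 7.75e-06). For the other 19 myeloid progenitor genes (median 0.70) and for the neutrophil markers (lowest change 0.47), this source cannot be told apart from a change within the LSK fraction, as late precursors hold the same transcripts. Committed progenitors outside the stem cell gate may have entered the knockout sort, since megakaryocyte-erythroid genes also rose (median 0.30, 95% bootstrap interval 0.03 to 0.46), and the Sca-1 gene that sets the gate was not analysed here. A shift of the LSK cells themselves towards the myeloid lineage would give these values as well.

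Immunoglobulin V segments differed between the groups by more than expression-matched genes did. Igkv19-93 had a mean of 3.87 in the knockout and 8.21 in control, and Ighv8-12 of 6.16 and 2.21, examples chosen after their values were seen. Of 113 segments tested, 63 were higher and 17 lower, and their median absolute change of 0.46 exceeded the 0.13 of expression-matched genes (random-draw permutation p = 1e-04, the smallest that 10000 draws can give). Arrays of a group may carry RNA from a single pool of cells, in which case p-values would measure technical spread, but the SD within groups was 1.82 times that of matched genes, between the bounds set for and against it. A strain difference at these loci cannot be told apart from it either: 21.9% of 137 flanking genes passed against 30.9% elsewhere, a bound first set against it and then withdrawn because a difference within the segments need not move their neighbours.

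A hypothesis that loss of miR-21 releases its listed targets as a set was tested on their median, which was -0.14 (95% bootstrap interval -0.23 to 0.02). The interval includes 0, and so by a bound at 0 the test neither bears the hypothesis out nor excludes it. The median of all genes tested was 0.07, above this interval, so as a set the listed targets did not rise against all genes. Some members, such as Tnfaip3, also belong to other lists that fell. A release hidden under such changes therefore stays open. Of the 44 targets 4 rose, including Pdcd4, and 17 fell, while 3630 of all 19010 genes rose.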
